A study of Cobetia marina with 12 samples.

How the data were processed

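The study measured RNA of Cobetia marina strain MM1IDA2H-1 grown in 96-well plates at 16, 35, 38 and 41 °C, with 3 libraries per temperature and 95 cultures pooled per library. Libraries were made with a stranded total RNA kit that depletes ribosomal RNA and were read as pairs of 150 bases. Per the submitters' processing notes the tools were HISAT2 2.2.0, Subread, featureCounts 2.0.6, edgeR and limma; their roles and order are not given, and the genome build is not given in the sources used here. The strand setting and the handling of reads that fit several genes are not given either.

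The authors deposited 3 tables, each with the 35 °C libraries and those of 1 other temperature. The unit of the library columns is signal: gene counts that the authors divided by an effective library size, with column totals from 908256 (35 °C, replicate 1) to 1099010 (16 °C, replicate 1). The 35 °C columns were identical in the 3 tables, so the 12 libraries were treated as normalised together. The fold change column of each deposited table is in log2, and the deposited p-value columns hold a raw p-value and one adjusted by the Benjamini-Hochberg method. The deposited tables list 3245 protein-coding genes with locus tags and a product, of which 44 have a gene symbol, so genes are named by product and tag. Products shared by several tags (choline dehydrogenase, superoxide dismutase, endopeptidase La) are named by tag. In each library all values were whole multiples of 1 step, within a tolerance of 0.001 of a step, and the step gave totals of 23345011 to 36888543 reads. Only 37 to 60 genes per library lay within 20 steps of 0, too few to treat the values as recovered counts, so the steps served for the depth, a filter of 50 reads and simulated data only. Replicates of a temperature differed by a chi-square of 82.0 to 425 per gene, so no library was a copy of another.

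The plan assumed counts and named limma for normalised values; since the unit is normalised, limma 3.58.1 with a trend was used in R 4.3.3 on log2 of signal plus 1. Genes with a signal of at least 1 in at least 3 libraries were tested, and p-values were adjusted over the genes tested by the Benjamini-Hochberg method with a threshold of 0.05. Each temperature was compared with 35 °C in its 6 libraries, and 41 with 38 °C and 16 with 41 °C in a fit of all 12. Gene lists were fixed before the data were examined, by symbol and product text. They cover heat shock chaperones and proteases, cold shock proteins and RNA remodelling, compatible solutes, flagellum and chemotaxis, ribosomal proteins, ATP synthase, respiratory chain, TCA cycle and glyoxylate shunt, iron acquisition, oxidative stress defence, fatty acid synthesis and membrane lipids, fatty acid degradation, SOS response and DNA repair, nitrogen assimilation, sulfur assimilation and cysteine synthesis, type VI secretion, type IV pili, branched-chain amino acid synthesis, methionine synthesis, arginine synthesis, aromatic amino acid and histidine synthesis, aminoacyl-tRNA synthetases, peptidoglycan and cell division, outer membrane biogenesis and envelope stress, exopolysaccharide and cyclic di-GMP, nucleotide synthesis, glycolysis, Entner-Doudoroff and gluconeogenesis, RNA polymerase and sigma factors. Another 4 lists had fewer than 5 tested genes and are given as counts: mobile elements and prophage, aromatic compound degradation, polyhydroxyalkanoate metabolism, TRAP transporters. A list of ribosomal and transfer RNA for library quality was dropped, since the tables hold no such genes and only RNA-modifying enzymes matched. The list test was camera with a preset correlation of 0.01, adjusted over 84 tests, beside camera with an estimated correlation and fry. Some products matched a list without doing what its name says, such as 3-isopropylmalate dehydrogenase in the TCA cycle list. They were kept, and the lists were rerun without them. That rerun left the fatty acid degradation list as it was (median -0.61 at 38 °C and -1.70 at 41 °C). Its genes in runs with enzymes of valine and leucine breakdown were thus not set aside. Overlaps between comparisons were set beside 100 simulated draws of unchanged groups against the same 35 °C libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

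Named genes followed a rule fixed before the data were examined. Per comparison these are the 8 largest rises and 8 largest falls among called genes with an annotated product, no overlap between groups and a mean of at least 10 at 1 temperature. To these come up to 4 called members of each list described and 2 going the other way, and a fixed set of stress, osmolyte and motility genes. Not every gene of that fixed set is given in the Results. At 38 °C those left out include endopeptidase La BFX80_04350 and superoxide dismutase BFX80_00430, which were not called (limma adjusted p = 0.0541 and 0.358). They also include choline dehydrogenase BFX80_10615, which was called (limma adjusted p = 0.0234). No product in the deposited tables matched deaD or katG of that set. Other genes carry the remark that they were chosen after their values were seen.

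The test was checked on simulated data with 50 genes changed at each of 4 fold changes. Every gene and library had 1 spread, a median over these libraries, so differences in spread between genes or temperatures were not simulated. At 1.25-fold the test called 62%, 60% and 68% of changed genes in the right direction for 16, 38 and 41 °C. At 1.5-fold it called 100%, 98% and 98%. Of unchanged genes it called 4 of 2992, 4 of 2994 and 12 of 2998. A list with an added shift was called, and 0 of 27 other lists were. Simulated genes varied independently of each other, so this cannot show how often camera calls unshifted lists of correlated genes. Alternatives tried were the replicate number as a block, library size alone and median-ratio scaling, no filter and the filter of 50 reads, added values of 0.1 and 5, all 12 libraries in 1 fit, a 2-fold demand and each library left out. An added alternative, limma's voom on reads worked out from the steps, was run once after the data were seen and then left out, because the values do not qualify as recovered counts. No other count-based test was run, and no analysis of gene position beyond locus tag order was made because no annotation was used.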

Results

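RNA of Cobetia marina strain MM1IDA2H-1, a marine bacterium, was sequenced after growth at 16, 35, 38 and 41 °C. Each temperature had 3 libraries, and each library came from 95 microplate cultures that were pooled at mid-exponential growth. The 35 °C libraries were the control of every comparison in the deposited tables. The tables give a normalised read count for 3245 protein-coding genes, of which 1024 carry a hypothetical product. Reads assigned to genes, worked out from the smallest step between values, ran from 23345011 (16 °C, replicate 2) to 36888543 (35 °C, replicate 3). Replicates are labelled as such, but nothing is said on separate days or batches, so a limma p-value below measures only the spread between the libraries fitted. A camera p-value compares the genes of a list with the other genes tested. With the preset correlation it also rests on that assumed value, which was not taken from the spread between these libraries. Comparisons with 35 °C used 6 libraries and the others all 12, less any left out. Values are means ± SD of the normalised signal with n = 3 libraries per temperature. Changes are log2 fold changes of signal plus 1, which understate the change of genes with low values. A principal component analysis used the genes with a signal of at least 1 in at least 3 of the 12 libraries. Its first component held 51.5% of the variance, the second 30.9% and the third 8.53%.

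The comparison of 16 with 35 °C asks which genes follow growth in the cold. At 16 °C 30 of 33 flagellum and chemotaxis genes, 44 of 57 ribosomal protein genes and 9 of 14 genes for cold-shock proteins and RNA remodelling rose, and 13 of 16 heat shock chaperone and protease genes fell. Each of these lists passed camera with the preset correlation and had an adjusted p = 0.638 with an estimated correlation. Flagellin (BFX80_08765), the filament subunit, averaged 428 ± 21.3 at 16 °C and 51.9 ± 16.8 at 35 °C (log2 fold change 3.06). The chaperonin GroL (BFX80_03860), which folds proteins, averaged 1685 ± 153 at 16 °C and 6891 ± 737 at 35 °C (log2 fold change -2.03). The cold-shock protein BFX80_12290, of a family of RNA chaperones, averaged 3684 ± 366 at 16 °C and 694 ± 111 at 35 °C (log2 fold change 2.41).

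Of 33 flagellum and chemotaxis genes 30 rose and 0 fell at 16 °C (31 rose and 0 fell adjusted over the list alone; median 1.62; camera adjusted p = 3.18e-09, and adjusted p = 0.638 with an estimated correlation). Examples are the motor stator gene MotA (BFX80_08560) with 370.4 ± 32.8 at 16 °C and 59.5 ± 16.6 at 35 °C, and the chemotaxis kinase gene CheA (BFX80_08570) with 388 ± 16.0 and 60.5 ± 19.0. The phosphatase gene CheZ (BFX80_08600) had 160.0 ± 1.32 at 16 °C and 24.1 ± 7.49 at 35 °C. Of 57 ribosomal protein genes 44 rose and 1 fell (45 rose and 1 fell adjusted over the list alone; median 0.63; camera adjusted p = 2.78e-09, and adjusted p = 0.638 with an estimated correlation). S21 (BFX80_02210) rose from 422 ± 57.1 to 2653 ± 149, and S20 (BFX80_00885) rose from 551 ± 83.7 to 1681 ± 141. L34 (BFX80_17185) was the member that fell, to 291 ± 40.3 from 35 °C values of 505, 2027 and 1707. Of 14 genes for cold-shock proteins and RNA remodelling 9 rose and 0 fell (9 rose and 0 fell adjusted over the list alone; median 0.46; camera adjusted p = 0.00605, and adjusted p = 0.638 with an estimated correlation). The cold-shock protein genes BFX80_11355 (log2 fold change 2.04, limma adjusted p = 4.38e-05) and BFX80_15385 (log2 fold change 0.71, limma adjusted p = 0.00537) rose, as did the exonuclease gene polyribonucleotide nucleotidyltransferase (BFX80_16415, log2 fold change 0.59, limma adjusted p = 0.00141). All 9 genes of type VI secretion, a contact-dependent toxin delivery system, passed the filter on low values. Of these 7 rose and 0 fell (7 rose and 0 fell adjusted over the list alone; median 0.64; camera adjusted p = 0.00243, and adjusted p = 0.638 with an estimated correlation). An example is the sheath protein gene EvpB (BFX80_10565) with 1337 ± 46.0 at 16 °C and 783 ± 52.9 at 35 °C.

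Of 16 heat shock chaperone and protease genes 13 fell and 1 rose at 16 °C (1 rose and 14 fell adjusted over the list alone; median -1.09; camera adjusted p = 5.73e-05, and adjusted p = 0.638 with an estimated correlation). DnaK (BFX80_16530) fell from 3982 ± 312 to 1706 ± 95.7, ClpB (BFX80_01020) from 5602 ± 790.0 to 1501 ± 260.0 and HtpG (BFX80_12225) from 1723 ± 125 to 508 ± 131. GroES (BFX80_03865), the partner of GroL, fell (log2 fold change -1.86, limma adjusted p = 4.84e-05), and so did the peptidase gene HslV (BFX80_01815, log2 fold change -1.72, limma adjusted p = 4.05e-05). The protease subunit gene ClpX (BFX80_04900) rose (log2 fold change 0.40, limma adjusted p = 0.0142). The gene of sigma-32 (BFX80_01455), the heat shock sigma factor, rose against the list (log2 fold change 0.64, limma adjusted p = 0.0167). The gene of RpoS (BFX80_04170), the general stress sigma factor, also rose (log2 fold change 0.62, limma adjusted p = 0.000543).

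Of the genes the naming rule allows, the largest rise was that of a DNA (cytosine-5-)-methyltransferase (BFX80_05455), from 13.1 ± 3.01 to 131 ± 17.9. Ketol-acid reductoisomerase (BFX80_01040), an enzyme of branched-chain amino acid synthesis, rose from 152 ± 17.3 to 991 ± 45.5, while the leucine branch enzyme 3-isopropylmalate dehydratase small subunit (BFX80_12095) fell from 406 ± 43.3 to 85.4 ± 6.24. The regulator BetI (BFX80_13965) and betaine-aldehyde dehydrogenase (BFX80_13970), which serve the synthesis of glycine betaine from choline, rose (2.88 and 2.31 on the log2 scale; limma adjusted p = 1.66e-05 and 2.26e-05). The ectoine synthesis genes for diaminobutyrate acetyltransferase (BFX80_08920), its transaminase (BFX80_08925) and L-ectoine synthase (BFX80_08930) fell (to 393 ± 26.2, 672 ± 49.6 and 103 ± 14.5 from 743 ± 188, 1285 ± 302 and 208 ± 49.2; limma adjusted p = 0.00474, 0.00374 and 0.00388). Ectoine and glycine betaine are compatible solutes, small molecules that balance external salt. Among the largest falls, the alpha-glucosidase gene (BFX80_10860) went from 77.7 ± 16.3 to 5.99 ± 1.93. The neighbouring transporter genes BFX80_10850, BFX80_10855 and BFX80_10865 fell (-2.87, -2.99 and -3.07 on the log2 scale). A TetR family regulator gene (BFX80_09700) fell from 89.1 ± 18.5 to 6.49 ± 0.924, and 4-carboxymuconolactone decarboxylase (BFX80_06125) from 303 ± 46.5 to 26.6 ± 0.787. The transporter gene LysE (BFX80_05055) fell from 127 ± 24.4 to 17.6 ± 1.12. Aldehyde dehydrogenase (BFX80_14710) fell to 67.1 ± 17.8, from 35 °C values of 289.6, 1030.3 and 297. The DNA repair recombinase gene RecA (BFX80_01935) fell (log2 fold change -0.75, limma adjusted p = 0.000920).

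In all, limma called 1784 of 3194 tested genes at 16 °C, 890 higher and 894 lower, and 433 of them changed at least 2-fold (192 higher, 241 lower). The groups did not overlap in 66.0% of tested genes, where chance gives 10%. The other 23 lists tested did not pass (camera adjusted p from 0.0554 to 0.957). Of these, oxidative stress defence passed without 16 °C replicate 3 (adjusted p = 0.0475) or 35 °C replicate 3 (0.0460), and ATP synthase passed without 35 °C replicate 2 (0.0453). Scaling by library size alone moved the median of all genes by -0.21 and gave 542 genes higher and 1332 lower, so the even split of directions holds relative to the authors' scaling. The 5 lists passed under that scaling too.

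**Figure D1:**
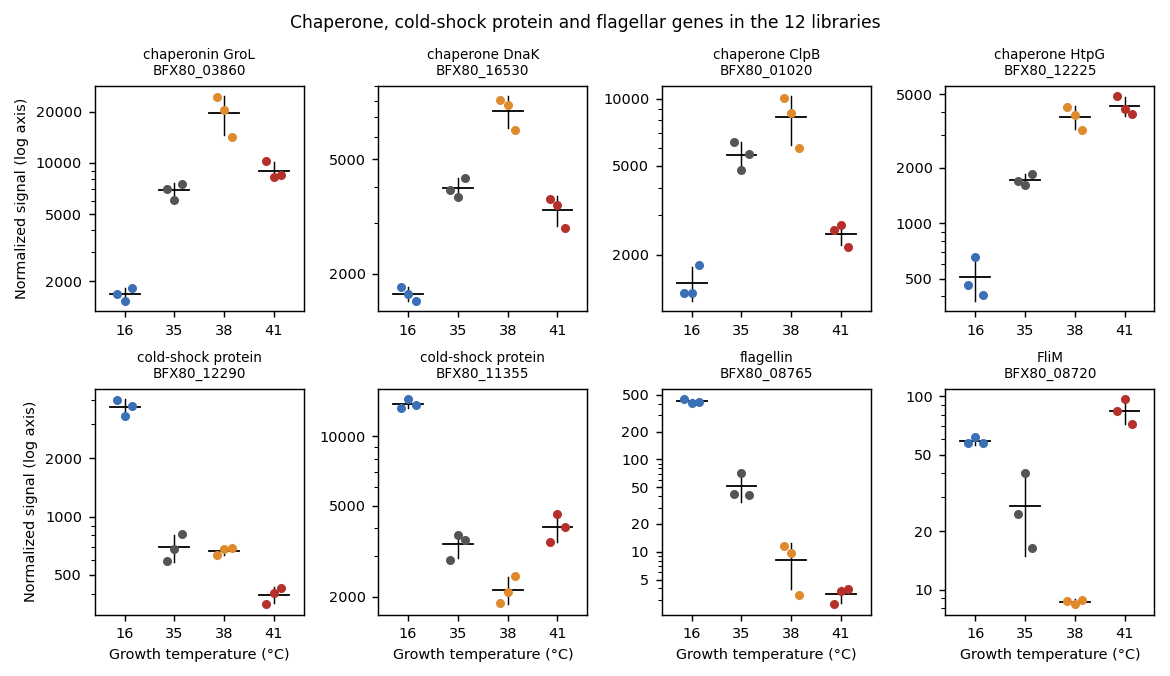
Normalised signal (log axis) of 4 chaperone genes, 2 cold-shock protein genes and 2 flagellar genes against growth temperature, with 1 point per library (n = 3), a horizontal line at the mean and a vertical line of 1 SD. GroL averaged 1685 ± 153, 6891 ± 737, 19711 ± 5146 and 9001 ± 1090.4 at 16, 35, 38 and 41 °C, and FliM averaged 8.66 ± 0.244 at 38 °C and 84.3 ± 12.5 at 41 °C.

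The comparison of 38 with 35 °C asks about growth a few degrees above the control. At 38 °C 8 of 16 heat shock genes rose, among them those of the chaperonin, and 27 of 33 flagellum and chemotaxis genes fell. Both lists passed camera with the preset correlation and had an adjusted p = 0.638 with an estimated correlation. Genes of an iron transporter and of a C4-dicarboxylate transporter fell as well. GroL averaged 19711 ± 5146 at 38 °C and 6891 ± 737 at 35 °C (log2 fold change 1.49). The porin gene BFX80_07605, for an outer membrane channel, averaged 17.5 ± 3.99 at 38 °C and 553 ± 60.1 at 35 °C (log2 fold change -4.92). Flagellin averaged 8.19 ± 4.26 at 38 °C and 51.9 ± 16.8 at 35 °C (log2 fold change -2.61).

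Of 16 heat shock genes 8 rose and 0 fell at 38 °C (9 rose and 0 fell adjusted over the list alone; median 0.48; camera adjusted p = 0.00184, and adjusted p = 0.638 with an estimated correlation). GroES (log2 fold change 1.54, limma adjusted p = 0.00417), HtpG (log2 fold change 1.13, limma adjusted p = 0.00205), DnaK (log2 fold change 0.88, limma adjusted p = 0.00424) and its exchange factor GrpE (BFX80_16535, log2 fold change 0.74, limma adjusted p = 0.00852) rose. In 38 °C replicate 3, which stood apart from the other 38 °C libraries, GroL was 14236, beside 24448 and 20449 in replicates 1 and 2. ClpB had 8232 ± 2042 at 38 °C and 5602 ± 790.0 at 35 °C (limma adjusted p = 0.0984). Sigma-32 had 1566 ± 519.9 and 939.9 ± 185 (limma adjusted p = 0.1003). Of the 33 flagellum and chemotaxis genes 0 rose and 27 fell (0 rose and 30 fell adjusted over the list alone; median -1.25; camera adjusted p = 4.99e-10, and adjusted p = 0.638 with an estimated correlation). MotA (BFX80_08560) fell from 59.5 ± 16.6 to 14.6 ± 3.96 and the hook-associated protein gene FlgK (BFX80_08685) from 69.4 ± 24.3 to 15.6 ± 0.414. Of the 57 ribosomal protein genes 16 rose and 1 fell (18 rose and 2 fell adjusted over the list alone; median 0.23; camera adjusted p = 0.000173, and adjusted p = 0.692 with an estimated correlation). S17 (BFX80_00645, log2 fold change 0.54, limma adjusted p = 0.00858) and S8 (BFX80_00670, log2 fold change 0.52, limma adjusted p = 0.00858) rose. The self-contained test fry did not call this list (adjusted p = 0.105). Its median was 0.15 without 38 °C replicate 3 (adjusted p = 0.00724). Of 21 aminoacyl-tRNA synthetase genes, which charge tRNA with amino acids, 8 rose and 0 fell (8 rose and 0 fell adjusted over the list alone; median 0.17; camera adjusted p = 0.00601, and adjusted p = 0.638 with an estimated correlation). Aspartate--tRNA ligase (BFX80_09215) rose from 1225 ± 86.3 to 1802 ± 104 and glutamate--tRNA ligase (BFX80_14625) from 273 ± 17.2 to 410.1 ± 12.6. This call was lost without 38 °C replicate 3 (adjusted p = 0.0577), and the median was 0.29 without 35 °C replicate 2 (adjusted p = 0.00127). With library size alone as the scaling the median of this list was 0.099 (camera adjusted p = 0.00635).

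Of 23 respiratory chain genes 7 rose and 2 fell at 38 °C (11 rose and 2 fell adjusted over the list alone; median 0.29; camera adjusted p = 0.00601, and adjusted p = 0.638 with an estimated correlation). Subunit II of ubiquinol oxidase (BFX80_14960) rose from 624 ± 50.8 to 942 ± 31.0, and the iron-sulfur subunit of succinate dehydrogenase (BFX80_14585) from 674 ± 13.8 to 1091 ± 127. Of 18 genes of glycolysis, the Entner-Doudoroff pathway and gluconeogenesis 9 rose and 0 fell (9 rose and 1 fell adjusted over the list alone; median 0.42; camera adjusted p = 0.0139, and adjusted p = 0.638 with an estimated correlation). Glucose-6-phosphate dehydrogenase (BFX80_13385) rose from 281 ± 28.4 to 569 ± 117 and phosphogluconate dehydratase (BFX80_04010), the entry of the Entner-Doudoroff pathway, from 217 ± 24.4 to 413 ± 80.8. Of 13 fatty acid degradation genes 0 rose and 7 fell (0 rose and 8 fell adjusted over the list alone; median -0.61; camera adjusted p = 0.000404, and adjusted p = 0.638 with an estimated correlation). Acyl-CoA dehydrogenase BFX80_04760 fell from 194 ± 31.0 to 46.4 ± 13.8 and enoyl-CoA hydratase BFX80_04770 from 196 ± 20.8 to 63.6 ± 9.89. Enzymes with these names also act in the breakdown of branched-chain amino acids. Of the 9 type VI secretion genes 0 rose and 5 fell (0 rose and 9 fell adjusted over the list alone; median -0.43; camera adjusted p = 0.00205, and adjusted p = 0.638 with an estimated correlation). An example is BFX80_10570, with 246 ± 14.3 at 38 °C and 330.0 ± 16.3 at 35 °C (limma adjusted p = 0.0155). That gene lost its call without 38 °C replicate 1 or 2 (adjusted p = 0.0506 and 0.0704) or 35 °C replicate 2 or 3 (0.0539 and 0.0572). Of 18 iron acquisition genes 2 rose and 9 fell (2 rose and 9 fell adjusted over the list alone; median -0.38; camera adjusted p = 0.0139, and adjusted p = 0.638 with an estimated correlation). This call was lost without 38 °C replicate 3 (camera adjusted p = 0.0629), although the median was then -0.47.

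The iron dicitrate transporter gene BFX80_07585, the permease genes BFX80_07590 and BFX80_07595 and the substrate-binding protein gene BFX80_07600 lie next to the porin in locus tag order. They fell (-4.21, -4.93, -4.76 and -4.94 on the log2 scale) at 38 °C. The siderophore-iron reductase gene FhuF (BFX80_11175) fell (log2 fold change -1.19, limma adjusted p = 0.000617), while a ferric siderophore reductase gene (BFX80_06810) rose (log2 fold change 0.71, limma adjusted p = 0.00386). Of the C4-dicarboxylate transporter genes, which take up acids such as succinate, BFX80_03965 fell from 564 ± 36.8 to 28.1 ± 12.8. Its permease genes BFX80_03970 and BFX80_03975 fell (-4.02 and -3.78 on the log2 scale). A substrate-binding protein gene of another C4-dicarboxylate transporter (BFX80_11600) rose from 47.4 ± 2.38 to 126 ± 36.3. The secretion protein gene HlyD (BFX80_16020) rose from 43.9 ± 7.83 to 147 ± 48.9, and the adjacent MFS transporter gene BFX80_16015 from 76.6 ± 8.21 to 224 ± 79.1. Superoxide dismutase BFX80_09125 rose (log2 fold change 1.03, limma adjusted p = 0.00245) and nickel superoxide dismutase (BFX80_09685) fell (log2 fold change -2.53, limma adjusted p = 0.000114). Both remove superoxide. RecA fell (log2 fold change -0.69, limma adjusted p = 0.00619).

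Among the 8 largest rises at 38 °C, 3 calls were lost when 1 library was left out. Glyceraldehyde-3-phosphate dehydrogenase BFX80_04015 rose from 478 ± 105 to 1427 ± 532 (limma adjusted p = 0.0126, and 0.0515 without 38 °C replicate 2). Glycerol-3-phosphate dehydrogenase BFX80_05215 rose from 98.5 ± 7.45 to 334 ± 188 (limma adjusted p = 0.0245, and 0.0835 without 38 °C replicate 2, 0.0741 without 35 °C replicate 1, 0.0723 without 35 °C replicate 2, 0.0675 without 35 °C replicate 3). MFS transporter BFX80_08165 rose from 13.9 ± 0.459 to 43.7 ± 21.8 (limma adjusted p = 0.0210, and 0.0718 without 38 °C replicate 2, 0.0616 without 35 °C replicate 1, 0.0618 without 35 °C replicate 2, 0.0646 without 35 °C replicate 3). The cold-shock protein gene BFX80_12290 had 669 ± 32.1 at 38 °C and 694 ± 111 at 35 °C (limma adjusted p = 0.830), while the cold-shock protein genes BFX80_11355 (log2 fold change -0.66, limma adjusted p = 0.0181) and BFX80_15385 (log2 fold change -0.66, limma adjusted p = 0.0158) fell. The call of BFX80_11355 was lost when 1 library was left out (adjusted p = 0.0573 without 38 °C replicate 1, 0.0748 without 38 °C replicate 2, 0.0569 without 35 °C replicate 2, 0.0661 without 35 °C replicate 3), as was that of BFX80_15385 (0.0595 without 38 °C replicate 1, 0.0668 without 38 °C replicate 2, 0.0501 without 35 °C replicate 3). The ectoine synthesis genes BFX80_08920, BFX80_08925 and BFX80_08930 had log2 fold changes of 0.01, -0.36 and -0.56 (limma adjusted p = 0.979, 0.176 and 0.0747).

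In all, limma called 853 of 3193 tested genes at 38 °C, 384 higher and 469 lower, and 204 changed at least 2-fold (44 higher, 160 lower). Library size alone as the scaling gave 249 higher and 576 lower, and the replicate number as a block gave 563 genes, 228 higher and 335 lower. The groups did not overlap in 46.0% of tested genes, where chance gives 10%. Without 38 °C replicate 1, 2 or 3 the count was 462, 354 or 1325, and without 35 °C replicate 1, 2 or 3 it was 427, 491 or 419. The other 19 lists did not pass (camera adjusted p from 0.0554 to 0.945), and the TCA cycle list passed without 38 °C replicate 3 (0.0428) or 35 °C replicate 1 (0.0438).

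The comparison of 41 with 35 °C asks about the warmest growth tested. At 41 °C 52 of 57 ribosomal protein genes and 16 of 21 aminoacyl-tRNA synthetase genes rose, and 12 of 13 fatty acid degradation genes and 19 of 28 nitrogen assimilation genes fell. Each of these lists passed camera with the preset correlation and had an adjusted p = 0.638 with an estimated correlation. The glycosyl transferase gene BFX80_06065, which adds sugars to a chain, averaged 21.7 ± 21.5 at 41 °C and 1093 ± 108 at 35 °C (log2 fold change -5.99). Ketol-acid reductoisomerase averaged 3425 ± 663 at 41 °C and 152 ± 17.3 at 35 °C (log2 fold change 4.47). A catalase gene (BFX80_06785), for an enzyme that breaks down hydrogen peroxide, averaged 96.7 ± 2.50 at 41 °C and 6.96 ± 2.23 at 35 °C (log2 fold change 3.65).

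Of the 57 ribosomal protein genes 52 rose and 1 fell at 41 °C (52 rose and 1 fell adjusted over the list alone; median 0.65; camera adjusted p = 4.99e-10, and adjusted p = 0.638 with an estimated correlation). L24 (BFX80_00655) rose from 548 ± 13.6 to 1194 ± 25.05 and S17 (BFX80_00645) from 507 ± 43.7 to 997 ± 38.6. Of the 21 aminoacyl-tRNA synthetase genes 16 rose and 0 fell (16 rose and 0 fell adjusted over the list alone; median 0.47; camera adjusted p = 0.00169, and adjusted p = 0.638 with an estimated correlation). The alpha subunit of phenylalanine--tRNA ligase (BFX80_05145) rose from 528 ± 53.5 to 1055 ± 12.6. Of 20 nucleotide synthesis genes 12 rose and 1 fell (12 rose and 1 fell adjusted over the list alone; median 0.38; camera adjusted p = 0.0139, and adjusted p = 0.638 with an estimated correlation). Ribonucleotide-diphosphate reductase subunit beta (BFX80_15410), needed for DNA precursors, rose from 633 ± 52.1 to 1487 ± 142. Of 9 methionine synthesis genes 8 rose and 1 fell (8 rose and 1 fell adjusted over the list alone; median 0.59; camera adjusted p = 0.0139, and adjusted p = 0.638 with an estimated correlation). The cobalamin-independent methionine synthase gene (BFX80_11025), annotated as a homocysteine methyltransferase, rose from 264 ± 23.3 to 1942 ± 257. The methionine synthase gene BFX80_08905 also rose (log2 fold change 0.91, limma adjusted p = 0.000107).

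Of the 13 fatty acid degradation genes 1 rose and 12 fell at 41 °C (1 rose and 12 fell adjusted over the list alone; median -1.70; camera adjusted p = 0.00184, and adjusted p = 0.638 with an estimated correlation). BFX80_04760 fell from 194 ± 31.0 to 12.7 ± 1.61 and enoyl-CoA hydratase BFX80_04665 from 167 ± 41.4 to 9.16 ± 1.28, while 2,4-dienoyl-CoA reductase (BFX80_15660) rose from 137 ± 9.72 to 456 ± 51.8. BFX80_04760 lies in a run of genes with 3-hydroxyisobutyrate dehydrogenase (BFX80_04775) and BFX80_04665 in one with isovaleryl-CoA dehydrogenase (BFX80_04675), enzymes of valine and leucine breakdown; these neighbours were chosen after their values were seen. Of 28 nitrogen assimilation genes 0 rose and 19 fell (0 rose and 19 fell adjusted over the list alone; median -0.47; camera adjusted p = 0.00580, and adjusted p = 0.638 with an estimated correlation). The urease subunit alpha gene (BFX80_06330) fell from 50.3 ± 0.659 to 25.6 ± 1.28 and the urea permease gene UrtC (BFX80_06300) from 86.9 ± 7.39 to 40.0 ± 3.42. Of 9 branched-chain amino acid synthesis genes 1 rose and 8 fell (1 rose and 8 fell adjusted over the list alone; median -0.66; camera adjusted p = 0.0497, and adjusted p = 0.638 with an estimated correlation). The rise was that of ketol-acid reductoisomerase. 3-isopropylmalate dehydratase large subunit (BFX80_12100) fell from 1633 ± 106 to 773 ± 32.2. The call of this list was lost with library size alone as the scaling (adjusted p = 0.0557) and with the replicate number as a block (0.0566). It was also lost without 41 °C replicate 1, 2 or 3 (adjusted p = 0.0524, 0.0571 and 0.0752) or 35 °C replicate 2 (0.0552). Of the 9 type VI secretion genes 0 rose and 7 fell (0 rose and 7 fell adjusted over the list alone; median -0.55; camera adjusted p = 0.0428, and adjusted p = 0.692 with an estimated correlation). This call was lost without 41 °C replicate 2 (adjusted p = 0.0555) or 35 °C replicate 2 (0.0934). EvpB fell from 783 ± 52.9 to 435 ± 35.6.

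The heat shock list did not pass at 41 °C (median -0.32; camera adjusted p = 0.228, and adjusted p = 0.778 with an estimated correlation); 3 of its genes rose and 10 fell (3 rose and 10 fell adjusted over the list alone). HtpG (log2 fold change 1.32, limma adjusted p = 4.48e-05) and GroES (log2 fold change 0.67, limma adjusted p = 0.00120) rose. GroL also rose (log2 fold change 0.38, limma adjusted p = 0.0252), but not without 41 °C replicate 1 (adjusted p = 0.0826) or 35 °C replicate 2 (0.0543). ClpB (log2 fold change -1.17, limma adjusted p = 0.000204), GrpE (log2 fold change -0.32, limma adjusted p = 0.0127) and the Clp protease subunit gene ClpA (BFX80_03615, log2 fold change -1.04, limma adjusted p = 7.69e-05) fell, and DnaK had 3341 ± 403 at 41 °C and 3982 ± 312 at 35 °C (limma adjusted p = 0.0757). Sigma-32 (log2 fold change -0.83, limma adjusted p = 0.00166) and RpoS (log2 fold change -0.62, limma adjusted p = 9.74e-05) fell. The flagellum list did not pass either (median 0.39; camera adjusted p = 0.752, and adjusted p = 0.945 with an estimated correlation), with 12 genes that rose and 10 that fell (12 rose and 10 fell adjusted over the list alone). Flagellin fell from 51.9 ± 16.8 to 3.45 ± 0.656, and the motor protein gene MotB (BFX80_05120) from 5715 ± 216 to 3164 ± 159, while the motor switch gene FliM (BFX80_08720) rose from 27.0 ± 12.1 to 84.3 ± 12.5 and the run BFX80_08705 to BFX80_08725 that holds it, with FliP, FliO and FliN, had a median of 1.42. The cold-shock protein gene BFX80_12290 fell (log2 fold change -0.80, limma adjusted p = 0.00113), while BFX80_11355 (log2 fold change 0.24, limma adjusted p = 0.148, and 0.034 with the replicate number as a block) and BFX80_15385 (log2 fold change -0.003, limma adjusted p = 0.984) were not called. The cold shock list, with 9 genes that rose and 1 that fell (9 rose and 1 fell adjusted over the list alone; median 0.37; camera adjusted p = 0.0554, and adjusted p = 0.748 with an estimated correlation), passed without 41 °C replicate 1 (0.0376), 35 °C replicate 2 (0.0341) or 35 °C replicate 3 (0.0462).

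Among the largest rises, the MFS transporter gene BFX80_08165 went from 13.9 ± 0.459 to 231 ± 32.01 and an RNA helicase gene (BFX80_11235) from 138 ± 33.0 to 1009.6 ± 126. A choline transporter gene (BFX80_06780) rose from 92.5 ± 18.7 to 655 ± 36.0, a flavin reductase gene (BFX80_11030) from 86.8 ± 12.9 to 628 ± 69.0 and glycerol-3-phosphate dehydrogenase (BFX80_05215) from 98.5 ± 7.45 to 597 ± 33.4. Among the largest falls, the aminotransferase gene DegT (BFX80_06070) went from 662 ± 77.0 to 12.9 ± 12.8 (41 °C libraries 5.55, 5.44 and 27.7) and the glycosyl transferase gene BFX80_06105 from 498 ± 84.4 to 8.63 ± 3.67. For BFX80_06065 the 41 °C libraries held 9.20, 9.34 and 46.5. The porin gene fell to 8.80 ± 0.950, and its neighbours BFX80_07590, BFX80_07595 and BFX80_07600 fell (-5.64, -5.69 and -6.03 on the log2 scale). A C4-dicarboxylate substrate-binding protein gene (BFX80_16100) fell from 239 ± 4.37 to 6.50 ± 0.997. Isocitrate lyase (BFX80_03560), the first enzyme of the glyoxylate shunt, fell from 309.7 ± 70.6 to 28.5 ± 4.22.

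In all, limma called 2186 of 3194 tested genes at 41 °C, 1058 higher and 1128 lower, and 616 changed at least 2-fold (177 higher, 439 lower). With median-ratio scaling 1109 were higher and 1089 lower, and with library size alone 922 and 1237. The groups did not overlap in 74.4% of tested genes, where chance gives 10%. The other 20 lists did not pass (camera adjusted p from 0.0554 to 0.821).

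**Figure D2:**
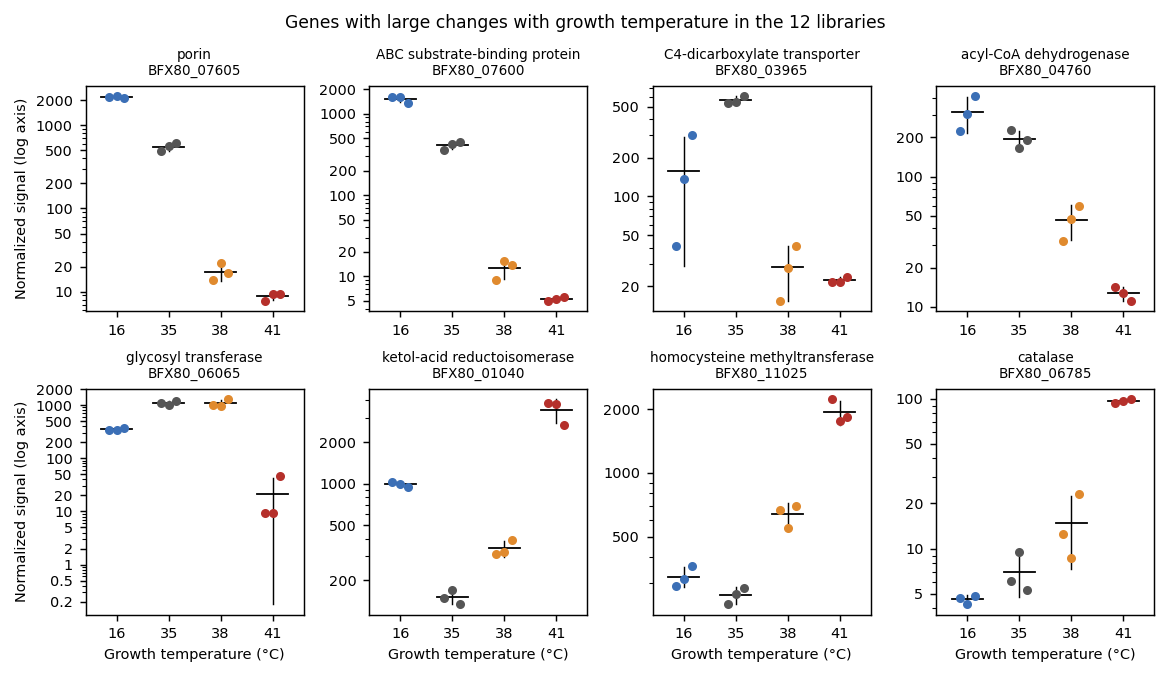
Normalised signal (log axis) of 8 genes with large changes against growth temperature, with 1 point per library (n = 3), a horizontal line at the mean and a vertical line of 1 SD. The porin averaged 2196 ± 51.1, 553 ± 60.1, 17.5 ± 3.99 and 8.80 ± 0.950 at 16, 35, 38 and 41 °C, and for the glycosyl transferase at 41 °C the SD is as large as the mean.

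**Figure D3:**
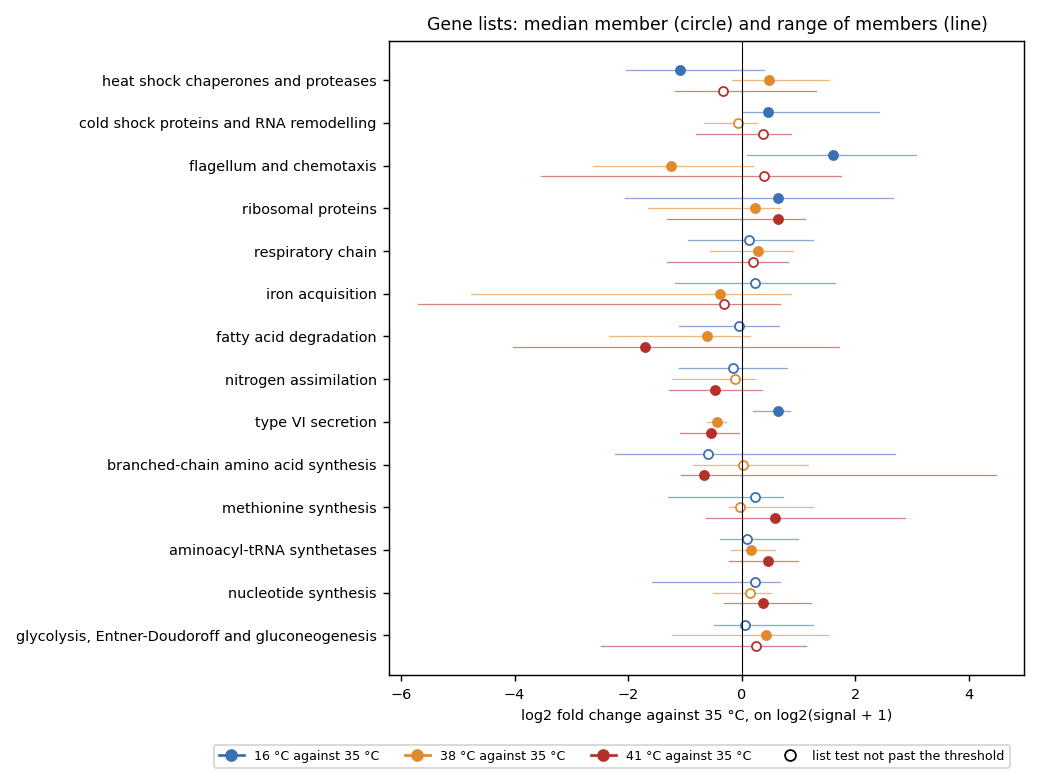
Log2 fold change against 35 °C of the 14 gene lists that passed the list test at 1 or more temperatures, with a circle at the median member and a line from the lowest to the highest member. Filled circles mark comparisons that passed with the preset correlation, and the flagellum list lies at 1.62 at 16 °C, -1.25 at 38 °C and 0.39 at 41 °C.

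The direct comparison of 41 with 38 °C, in a fit of all 12 libraries, asks which genes differ between the warm temperatures, and the shared controls cancel in it. FliM (BFX80_08720), a motor switch protein gene, averaged 84.3 ± 12.5 at 41 °C and 8.66 ± 0.244 at 38 °C (log2 fold change 3.13). The M-ring protein gene FliF (BFX80_08755) averaged 85.6 ± 12.1 at 41 °C and 8.68 ± 2.17 at 38 °C (log2 fold change 3.18), and the flagellar sigma factor gene FliA (BFX80_08770) averaged 51.4 ± 8.57 at 41 °C and 5.85 ± 0.780 at 38 °C (log2 fold change 2.93). The rod gene FlgC (BFX80_08640) and the rod modification gene BFX80_08645 were also higher (2.91 and 2.78 on the log2 scale; limma adjusted p = 7.16e-06 and 1.31e-05). Ketol-acid reductoisomerase (log2 fold change 3.31, limma adjusted p = 9.78e-08), catalase BFX80_06785 (log2 fold change 2.73, limma adjusted p = 1.57e-05) and RNA helicase BFX80_11235 (log2 fold change 3.03, limma adjusted p = 2.4e-06) were higher at 41 °C as well. BFX80_06065, BFX80_06070 and BFX80_06105 were lower at 41 °C by log2 fold changes of -5.99, -5.99 and -5.69. D-amino acid dehydrogenase small subunit (BFX80_04980) averaged 319 ± 54.5 at 41 °C and 2827 ± 492 at 38 °C, and the AsnC family regulator gene BFX80_05065 averaged 36.5 ± 4.28 and 327 ± 62.3. L-serine ammonia-lyase (BFX80_02240) averaged 152 ± 2.19 at 41 °C and 1199 ± 229 at 38 °C. Formyltetrahydrofolate deformylase (BFX80_14890) averaged 19.9 ± 2.11 and 163 ± 39.9. CsgG (BFX80_17255), the export pore for curli fibres, averaged 136 ± 83.7 and 856 ± 105; its 41 °C libraries held 94.8, 80.3 and 232. In all, limma called 2078 of 3201 genes, 1028 higher and 1050 lower at 41 °C, and 547 at least 2-fold (162 higher, 385 lower). With median-ratio scaling 1046 were higher and 1025 lower, and with library size alone 1018 and 1045. The groups did not overlap in 70.1% of tested genes, where chance gives 10%.

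Between 16 and 41 °C limma called 2213 of 3201 genes, 1162 higher and 1051 lower at 16 °C, and 811 at least 2-fold (498 higher, 313 lower). The groups did not overlap in 77.9% of tested genes, where chance gives 10%. Scaling by library size alone moved the median of all genes by -0.14 in this comparison and gave 986 genes higher and 1280 lower at 16 °C. The porin gene averaged 2196 ± 51.1 at 16 °C and 8.80 ± 0.950 at 41 °C (log2 fold change 7.81), and flagellin averaged 428 ± 21.3 at 16 °C and 3.45 ± 0.656 at 41 °C (log2 fold change 6.60). GroL averaged 1685 ± 153 at 16 °C and 9001 ± 1090.4 at 41 °C (log2 fold change -2.41), and catalase BFX80_06785 averaged 4.61 ± 0.308 at 16 °C and 96.7 ± 2.50 at 41 °C (log2 fold change -4.12). In list tests that were not planned, heat shock chaperones and proteases had a median of -0.69 (2 genes higher and 9 lower at 16 °C, 2 and 9 adjusted over the list alone; camera adjusted p = 0.0248); flagellum and chemotaxis had a median of 1.30 (22 genes higher and 1 lower at 16 °C, 22 and 1 adjusted over the list alone; camera adjusted p = 0.00104); fatty acid degradation had a median of 1.15 (10 genes higher and 1 lower at 16 °C, 10 and 1 adjusted over the list alone; camera adjusted p = 0.0212); type VI secretion had a median of 1.13 (8 genes higher and 0 lower at 16 °C, 9 and 0 adjusted over the list alone; camera adjusted p = 0.00230); aminoacyl-tRNA synthetases had a median of -0.36 (2 genes higher and 14 lower at 16 °C, 2 and 14 adjusted over the list alone; camera adjusted p = 0.0245). With an estimated correlation each of these 5 lists had an adjusted p = 0.767.

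Calls shared by 2 comparisons were counted over 3189 genes. At 38 and 41 °C, 246 genes were higher and 331 lower than at 35 °C in both, where independent lists would share 126 and 166. Opposite directions were called for 48 genes higher at 38 and lower at 41 °C and 31 the other way, where independent lists give 135 and 155. In 100 simulated draws of unchanged groups against the same 35 °C libraries, 0 genes were higher and on average 0.01 lower in both. Unchanged groups are rarely called at all, so this count cannot show how many shared calls the controls add among genes that change. The covariance of the 2 sets of fold changes was 0.302 beside 0.0158 in the simulation. Their correlation was 0.511 beside 0.504 and the share of genes with the same sign 61.9% beside 66.6%. The simulated correlation and share follow from how the draws were made, with a shared part and a separate part of equal spread. For no pair of temperatures do they show what the shared controls add among genes that change. For 16 and 41 °C, 349 genes were higher and 435 lower in both (independent 293 and 316, simulated 0 and 0.01). The covariance was 0.15, the correlation 0.194 and the same sign held in 56.4% of genes (simulated 0.0158, 0.504 and 66.6%). There 250 were higher at 16 and lower at 41 °C and 206 the other way (independent 313 and 296). For 16 and 38 °C, 109 were higher and 153 lower in both (independent 106 and 131, simulated 0 and 0.01). The covariance was -0.0406, the correlation -0.0923 and the same sign held in 46.7% (simulated 0.0158, 0.504 and 66.6%). More genes went in opposite directions, 172 higher at 16 and lower at 38 °C and 132 the other way (independent 130 and 107). With the replicate number as a block 159 genes were shared by 16 and 38 °C in place of 262. Part of an excess over independent lists may come from the shared 35 °C libraries, since 3 controls cannot be split between comparisons. Over all 3 comparisons 84 genes were called higher and 120 lower each time.

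Lists that passed in none of the 3 comparisons with 35 °C are given with counts only; where no second pair of counts follows, the counts adjusted over the list alone were the same. Of 28 compatible solutes genes, 7 rose and 13 fell (7 and 14 adjusted over the list alone) at 16 °C, 8 rose and 3 fell (8 and 6 adjusted over the list alone) at 38 °C and 9 rose and 12 fell at 41 °C. Among 8 genes of ATP synthase, 5 rose and 0 fell (7 and 0 adjusted over the list alone) at 16 °C, 0 rose and 1 fell at 38 °C and 0 rose and 1 fell at 41 °C. For TCA cycle and glyoxylate shunt, with 16 genes tested, 4 rose and 3 fell at 16 °C, 4 rose and 2 fell (7 and 3 adjusted over the list alone) at 38 °C and 3 rose and 8 fell (3 and 10 adjusted over the list alone) at 41 °C. Of 25 oxidative stress defence genes, 12 rose and 4 fell (15 and 4 adjusted over the list alone) at 16 °C, 7 rose and 2 fell at 38 °C and 10 rose and 8 fell (11 and 8 adjusted over the list alone) at 41 °C. Among 26 genes of fatty acid synthesis and membrane lipids, 10 rose and 4 fell at 16 °C, 5 rose and 1 fell at 38 °C and 13 rose and 5 fell at 41 °C. For SOS response and DNA repair, with 19 genes tested, 6 rose and 7 fell at 16 °C, 2 rose and 1 fell at 38 °C and 7 rose and 5 fell at 41 °C. Of 12 sulfur assimilation and cysteine synthesis genes, 4 rose and 0 fell at 16 °C, 2 rose and 1 fell at 38 °C and 7 rose and 1 fell at 41 °C. Among 8 genes of type IV pili, 3 rose and 1 fell at 16 °C, 0 rose and 2 fell at 38 °C and 1 rose and 4 fell at 41 °C. For arginine synthesis, with 11 genes tested, 1 rose and 4 fell (1 and 3 adjusted over the list alone) at 16 °C, 1 rose and 0 fell at 38 °C and 5 rose and 3 fell at 41 °C. Of 25 aromatic amino acid and histidine synthesis genes, 6 rose and 2 fell (4 and 2 adjusted over the list alone) at 16 °C, 3 rose and 0 fell at 38 °C and 10 rose and 3 fell (8 and 2 adjusted over the list alone) at 41 °C. Among 29 genes of peptidoglycan and cell division, 12 rose and 3 fell at 16 °C, 2 rose and 4 fell at 38 °C and 12 rose and 9 fell at 41 °C. For outer membrane biogenesis and envelope stress, with 22 genes tested, 3 rose and 7 fell at 16 °C, 3 rose and 2 fell at 38 °C and 2 rose and 9 fell at 41 °C. Of 7 exopolysaccharide and cyclic di-GMP genes, 3 rose and 3 fell at 16 °C, 1 rose and 1 fell at 38 °C and 0 rose and 5 fell at 41 °C. Among 13 genes of RNA polymerase and sigma factors, 4 rose and 3 fell at 16 °C, 1 rose and 1 fell (0 and 0 adjusted over the list alone) at 38 °C and 7 rose and 4 fell (8 and 4 adjusted over the list alone) at 41 °C. Lists that passed at another temperature gave these counts where they did not pass. At 16 °C, 9 rose and 3 fell of the 23 respiratory chain genes, 5 rose and 4 fell of the 18 iron acquisition genes, 3 rose and 3 fell (1 and 3 adjusted over the list alone) of the 13 fatty acid degradation genes, 3 rose and 12 fell of the 28 nitrogen assimilation genes, 1 rose and 6 fell (2 and 6 adjusted over the list alone) of the 9 branched-chain amino acid synthesis genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone) of the 9 methionine synthesis genes, 7 rose and 1 fell (2 and 1 adjusted over the list alone) of the 21 aminoacyl-tRNA synthetases genes, 11 rose and 3 fell of the 20 nucleotide synthesis genes, 5 rose and 3 fell of the 18 glycolysis, Entner-Doudoroff and gluconeogenesis genes. At 38 °C, 0 rose and 2 fell of the 14 cold shock proteins and RNA remodelling genes, 0 rose and 3 fell (0 and 2 adjusted over the list alone) of the 28 nitrogen assimilation genes, 1 rose and 2 fell of the 9 branched-chain amino acid synthesis genes, 2 rose and 0 fell of the 9 methionine synthesis genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone) of the 20 nucleotide synthesis genes. At 41 °C, 9 rose and 4 fell of the 23 respiratory chain genes, 2 rose and 10 fell of the 18 iron acquisition genes, 8 rose and 7 fell of the 18 glycolysis, Entner-Doudoroff and gluconeogenesis genes. The median and the mean of a list had opposite signs, or a sign opposite to the test, for the following lists. At 16 °C these were TCA cycle and glyoxylate shunt (median 0.04, mean -0.11), SOS response and DNA repair (median 0.12, mean -0.06), outer membrane biogenesis and envelope stress (median -0.09, mean 0.01), exopolysaccharide and cyclic di-GMP (median -0.02, mean 0.37). At 38 °C these were SOS response and DNA repair (median 0.05, mean -0.03), branched-chain amino acid synthesis (median 0.03, mean -0.05), methionine synthesis (median -0.03, mean 0.17), exopolysaccharide and cyclic di-GMP (median -0.01, mean 0.02), RNA polymerase and sigma factors (median -0.01, mean -0.01). At 41 °C these were ATP synthase (median 0.10, mean -0.03), oxidative stress defence (median -0.01, mean 0.06), arginine synthesis (median 0.29, mean -0.04), glycolysis, Entner-Doudoroff and gluconeogenesis (median 0.25, mean -0.24).

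In the authors' deposited table for 16 °C, 1786 genes had an adjusted p under 0.05 (904 higher, 882 lower), and 1665 of them were called here in the same direction. The authors' deposited table for 38 °C held 1133 such genes (566 higher, 567 lower), of which 810 were called here in the same direction. The authors' deposited table for 41 °C held 2078 (1011 higher, 1067 lower), of which 2028 were called here in the same direction.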

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

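The list tests of 41 against 38 °C and the test of scaling were chosen only after the results at 38 and 41 °C had been seen; what the test of single libraries would show was written before its values were computed, and the count of splits was planned. Each list below is given because its change against 35 °C differed between 38 and 41 °C in a direct test, camera on the difference between these temperatures over 28 lists. With an estimated correlation 0 of these 7 lists passed (adjusted p = 0.573 for each), 0 at an unadjusted p under 0.05, while fry called 19 of the 28 lists.

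The heat shock list was higher at 38 °C than at 35 °C (median 0.48) and lay at -0.32 at 41 °C; the median difference of 41 minus 38 °C was -1.06 (camera adjusted p = 0.00301), with 12 of 16 genes lower and 1 higher. A scaling factor moves every gene of a library alike, while the list lay at -1.05 from the median of all tested genes (quartiles -1.09 and -0.46). A factor per library does not produce such a distance. But the list was picked because camera set it apart from the other genes, so this test could hardly have come out otherwise. Library size alone moved the median of all tested genes by only -0.000518 and tested nothing. A single deviating library does not account for the difference of the list between 41 and 38 °C. The weakest median over the left-out libraries was -0.93, without 38 °C replicate 1. Over 10 splits of the 6 libraries, the real one called 2078 genes and the highest other 4. That count covers all genes and does not test the heat shock list. Every other split mixes both temperatures within a group, which widens the spread. Also, 1 of 10 splits is too few for a share under 0.05. A response of the cells to temperature stays open as a biological explanation that was not tested, and so does any difference between the cultures other than temperature.

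Flagellum and chemotaxis genes differed between 41 and 38 °C by a median of 1.35 (camera adjusted p = 4.83e-06; 26 genes higher and 2 lower of 33), from medians of -1.25 at 38 °C and 0.39 at 41 °C against 35 °C. Ribosomal protein genes differed between 41 and 38 °C by a median of 0.40 (camera adjusted p = 4.83e-06; 39 genes higher and 0 lower of 57), from medians of 0.23 at 38 °C and 0.65 at 41 °C against 35 °C. Genes for cold-shock proteins and RNA remodelling differed between 41 and 38 °C by a median of 0.52 (camera adjusted p = 0.0219; 10 genes higher and 1 lower of 14), from medians of -0.07 at 38 °C and 0.37 at 41 °C against 35 °C. TCA cycle and glyoxylate shunt genes differed between 41 and 38 °C by a median of -0.71 (camera adjusted p = 0.0251; 2 genes higher and 12 lower of 16), from medians of 0.39 at 38 °C and -0.44 at 41 °C against 35 °C. Fatty acid degradation genes differed between 41 and 38 °C by a median of -1.20 (camera adjusted p = 0.0251; 1 genes higher and 11 lower of 13), from medians of -0.61 at 38 °C and -1.70 at 41 °C against 35 °C. That call was lost without 38 °C replicate 3 (median -1.06, adjusted p = 0.0637). Methionine synthesis genes differed between 41 and 38 °C by a median of 0.61 (camera adjusted p = 0.0301; 8 genes higher and 1 lower of 9), from medians of -0.03 at 38 °C and 0.59 at 41 °C against 35 °C.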

How the results depend on the processing

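Alternatives fixed before the data were examined were library scaling, the filter on low values, the value added before the log, the replicate block, leaving out each library, and the list test; the fit of all 12 libraries, lists without stray members, lists under other scalings, the alternatives for 16 against 41 °C, the block, scaling and 12-library overlaps, and for 41 against 38 °C the scaling by library size, the stricter filter, the added values and the 2-fold demand were chosen after the data were seen. No called named gene turned its direction under the replicate block, median-ratio scaling, the fit of all 12 libraries or with 1 library left out. Named genes were not checked under the other settings, and uncalled ones only where they gained a call. No called list turned its direction in the list alternatives or in its weakest fit with 1 library left out. The larger of the 2 directions among called genes did turn: with median-ratio scaling at 16 °C (895 higher, 893 lower), at 41 °C (1109 and 1089) and for 41 against 38 °C (1046 and 1025), with library size alone for 16 against 41 °C (986 and 1280), and at 38 °C without its replicate 3 (664 and 661). At 16 °C it also turned in the fit of all 12 libraries (891 and 879) and without 16 °C replicate 1 (766 and 744) or 35 °C replicate 1, 2 or 3 (758 and 719, 855 and 841, 767 and 759). Demanding a 2-fold change as well left 433 genes at 16 °C, 204 at 38 °C, 616 at 41 °C, 547 for 41 against 38 °C and 811 for 16 against 41 °C, by construction. Replicate numbers did not pair the libraries: 4 of 18 correlations between groups were over 0.1 (-0.135 to 0.292), and 5 of 12 libraries had their best match under their own number. With that number as a block, 563 genes were called at 38 °C, and 159 genes were shared by 16 and 38 °C in place of 262; the block leaves fewer residual degrees of freedom. Simulated unchanged groups shared 0.01 genes where 262, 784 and 578 were shared, counted over all genes tested in both comparisons of a pair. Such groups are rarely called at all, so this cannot show what the shared controls add among genes that change. Leaving out 1 library gave 1464 to 1738 genes at 16 °C, 354 to 1325 at 38 °C, 1962 to 2205 at 41 °C, 1831 to 2160 for 41 against 38 °C and 2049 to 2316 for 16 against 41 °C. The lists called were then 5 to 6 at 16 °C, 8 to 10 at 38 °C and 6 to 9 at 41 °C. With an estimated correlation 0 lists passed at 16, 38 and 41 °C in place of 5, 9 and 8 (0, 0 and 1 at an unadjusted p under 0.05), and the self-contained test fry called 19, 11 and 21; the cause was not tested. Of 792 results for named genes, 39 lost their call and 2 gained one under the block, 2 lost it with median-ratio scaling and none gained one, and 95 lost it and 9 gained it when 1 library was left out. In the fit of all 12 libraries, taken for the comparisons with 35 °C alone, 442 were the same, 11 lost their call and 6 gained one. Of 22 called lists, ribosomal proteins at 38 °C were not called by fry (adjusted p = 0.105), and branched-chain amino acid synthesis at 41 °C was lost under the block (0.0566) and with library size alone (0.0557). A count-based test (DESeq2) was not run because the unit is normalised, and leaving out ribosomal and transfer RNA genes was not run because the tables hold none. Small changes were often missed in data simulated with the depth and number of these libraries and 1 median spread for every gene. There 62%, 60% and 68% of genes changed 1.25-fold were called at 16, 38 and 41 °C. Differences in spread between genes or temperatures were not simulated. Depth alone was not varied.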

Other observations

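The tests of the depth of 38 °C replicate 3, of 41 °C replicate 3 and of neighbouring genes at 41 °C were chosen after the results had been seen, as was the set of 99 genes added below; those of mixing in 38 °C replicate 3 and of neighbouring genes at 16 and 38 °C were written before their values were computed, and the counts of splits were planned; the genes named here were chosen after their values were seen. Genes next to each other in locus tag order changed together. At 41 °C, 21 runs of at least 5 consecutive genes fell at least 2-fold, 148 genes in all, and 2 runs rose (11 genes). At 38 °C, 11 runs fell (70 genes) and none rose. The run BFX80_04655 to BFX80_04675 (5 genes, median -4.03), with isovaleryl-CoA dehydrogenase and hydroxymethylglutaryl-CoA lyase, enzymes of leucine breakdown, fell at 41 °C, and its 5 genes fell at 38 °C (median -2.34). The run BFX80_04720 to BFX80_04780 (13 genes, median -2.77) fell at 41 °C; it holds methylmalonate-semialdehyde and 3-hydroxyisobutyrate dehydrogenases, enzymes of valine breakdown, beside allophanate hydrolase, glyoxalase, rhodanese, a MerR regulator and hypothetical proteins. Part of it fell, from BFX80_04735, at 38 °C (10 genes, median -1.46). The run BFX80_16070 to BFX80_16105 (8 genes, median -3.17), with genes for a glycine betaine transporter, gamma-butyrobetaine dioxygenase and a C4-dicarboxylate transporter, fell at 41 °C; of the same stretch BFX80_16070 to BFX80_16100 (7 genes, median -2.32) fell at 38 °C and BFX80_16080 to BFX80_16100 (5 genes, median -1.65) at 16 °C. The run BFX80_17240 to BFX80_17265 (6 genes, median -2.93), with the curli transport genes CsgF and CsgG and hypothetical proteins, fell at 41 °C as well.

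At 16 °C, 6 runs fell (52 genes) and 8 rose (74 genes). The run BFX80_07585 to BFX80_07605 (5 genes, median 1.64), with the porin and iron transporter genes, rose at 16 °C, and the same 5 genes fell at 38 °C (median -4.92) and, with BFX80_07610, at 41 °C (6 genes, median -5.67). A run with formate dehydrogenase genes, BFX80_09420 to BFX80_09455 (8 genes, median 2.15), rose, as did BFX80_05955 to BFX80_06005 (11 genes, median 2.07), hypothetical proteins and the polysaccharide export protein Wza. Nickel superoxide dismutase lies in the run BFX80_09670 to BFX80_09690 (5 genes, median 1.73), which rose. The run BFX80_06040 to BFX80_06150 (23 genes, median -1.63) fell, with genes for glycosyl transferases, an aminotransferase, 4-carboxymuconolactone decarboxylase, an RpiR regulator, ethanolamine ammonia-lyase and hypothetical proteins; at 41 °C its part BFX80_06040 to BFX80_06105 (14 genes, median -5.75) fell and its part BFX80_06120 to BFX80_06145 (6 genes, median 1.49) rose. The runs BFX80_08555 to BFX80_08625 (15 genes, median 2.46), BFX80_08640 to BFX80_08690 (11 genes, median 1.61) and BFX80_08705 to BFX80_08765 (13 genes, median 1.32), with flagellar and chemotaxis genes, rose at 16 °C. At 38 °C BFX80_08580 to BFX80_08615 (8 genes, median -1.44), BFX80_08660 to BFX80_08690 (7 genes, median -1.27) and BFX80_08750 to BFX80_08770 (5 genes, median -1.33) fell; at 41 °C BFX80_08580 to BFX80_08600 (5 genes, median -1.40) fell and BFX80_08705 to BFX80_08725 (5 genes, median 1.42), with FliP, FliO, FliN and FliM, rose. The longest runs held 14 genes at 41 °C, 10 at 38 °C and 23 at 16 °C, where 1000 shuffles of the gene order reached at most 8, 5 and 6. These lengths are consistent with neighbouring genes sharing their change, as genes of 1 operon would; no operon map was used here. Of the lists too small to test, aromatic compound degradation had 3 genes that rose and 1 that fell of 4 at 16 °C, and 2 that rose and 0 that fell at 38 and at 41 °C. Of 3 polyhydroxyalkanoate genes 2 rose and 1 fell at 16 °C, 0 rose and 1 fell at 38 °C, and 0 rose and 2 fell at 41 °C. Of 3 mobile element genes 1 rose and 1 fell at 16 °C, none changed at 38 °C and 2 fell at 41 °C. Of 3 TRAP transporter genes 1 rose at 16 °C, 1 fell at 38 °C and 2 fell at 41 °C.

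38 °C replicate 3 lay apart from replicates 1 and 2, and leaving it out raised the count of called genes from 853 to 1325. Its depth was like theirs (reads 0.998 times their mean), which argues against sequencing depth. RNA of a 35 °C culture mixed into it would need the same share of such RNA from every gene. The 80 genes at least 2-fold higher in replicates 1 and 2 than at 35 °C needed a median of 71.2% (quartiles 49.7 and 82.6). The 45 genes at least 4-fold lower there needed 5.80% (0.399 and 16.3), a difference of 65.4 points. Replicate 3 was left out of this choice, which by itself can draw it towards 35 °C in either set. A like-for-like set added later, 99 genes 2- to 4-fold lower, needed 15.6% (2.61 and 40.1), so a single mixing share is not supported; a culture at another growth stage stays open and was not tested.

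41 °C replicate 3 was higher than replicates 1 and 2 in the run BFX80_06040 to BFX80_06105, with glycosyl transferase genes (BFX80_06065 had 9.20, 9.34 and 46.5), and in the run with curli genes (CsgG, BFX80_17255, had 94.8, 80.3 and 232, and BFX80_17260 had 7.17, 5.84 and 31.2). RNA of a 35 °C culture could raise the first run at a median share of 3.41%. But 21 other genes, at least 20-fold lower in 41 °C replicates 1 and 2 than at 35 °C, needed 0.0129% (quartiles -0.338 and 0.909). Scaling or depth acts on all genes of a library alike, while the log2 ratio of that run lay 2.11 above the median of all genes (quartiles 1.23 and 2.23). A factor on the library does not produce such a distance. But the run was chosen after its high ratio was seen, so this test could hardly have come out otherwise. A subset of cells that kept these genes on, or a variant among the pooled cultures, stays open and was not tested. In the same library a transporter gene (BFX80_16770) had 1254 beside 37.7 and 42.8, and a tyrosine recombinase gene XerC (BFX80_16650) had 987 beside 173 and 144.

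The 10 splits of 6 libraries are too few for a share under 0.05 in each comparison: the real split called 1784 genes for 16 against 35 °C and the highest other 0, 853 and 0 for 38 against 35 °C, 2186 and 0 for 41 against 35 °C, and 2213 and 0 for 16 against 41 °C. Every other split mixes both temperatures within a group, which widens the spread and lowers its count.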
